A study of Homo sapiens with 12 samples.

How the data were processed

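RNA was sequenced from 3 derivatives of Kelly, a human neuroblastoma cell line that carries an amplified MYCN gene and has the neuronal-like, or adrenergic, character of this tumour. Each derivative carries a short hairpin RNA (shRNA) that is transcribed when doxycycline is added: an shRNA against RCOR1 (the shRCOR1 line), an shRNA against RCOR2 (the shRCOR2 line) or a control shRNA (the shCTRL line). RCOR1 and RCOR2 encode RCoR1 and RCoR2, related scaffold proteins that join the histone demethylase KDM1A to histone deacetylases. Cells of each line were left untreated or given 2 µg/mL doxycycline, here called induced, which makes 6 groups of 2 libraries and 12 libraries in all. The sample titles, the time label and the series design give 72 h of induction, while the treatment protocol mentions 24 or 48 h, so the length of the treatment is stated in conflicting ways and 72 h is used here only as the label. The labels do not say whether the replicates of a group are separate cultures, so the p-values measure the spread between these samples only. Total RNA went into directional NEBNext Ultra II libraries; whether poly(A) selection or ribosomal RNA depletion came first is not given in the sources used here.

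Per the submitters' processing notes, Trim Galore 0.6.7 (which trims adapters), HISAT2 2.2.1 (which aligns reads) and StringTie 2.1.7 (which assembles and quantifies transcripts) were used, with the builds GRCh38 and hg38. The annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here. Each library has 1 deposited gene abundance file in the layout of StringTie. The deposited TPM (a length-normalised abundance) are scaled by the authors to the same total in every library, so they measure a share of the RNA and not an amount per cell. The deposited FPKM (fragments scaled by gene length and library size) in the same files were used as an alternative. The deposited coverage signal, the mean number of reads over each base of a gene, was used to compare depths. All 12 files hold the same 60660 gene identifiers; 60463 matched the gene name table, 58429 have a type in GENCODE v29, and 110 symbols stand at more than 1 identifier. GENCODE v29 supplied gene types, transcript GC content and length, and 3′ untranslated regions (3′ UTRs), and no coordinates. A gene and an overlapping or antisense gene, or close paralogs, may share reads in these values, since neither the strand setting nor the multimapping rule is known.

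The files hold no read counts, and whole reads could not be recovered from the values, so no counting intervals are given. The ratio of coverage to FPKM, which grows with the number of mapped fragments, ran from 13.1 to 28.3, so the deepest library was 2.16 times as deep as the shallowest. Between 14758 and 16026 genes reached a TPM of 1 per library. Mitochondrial transcripts took 13.3% to 21.4% of TPM and more in replicate 2 than in replicate 1 of every group. Within groups, the Pearson correlation of log2(TPM + 1) between replicates across genes was 0.967 to 0.990.

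Genes with a TPM of at least 1 in at least 2 libraries were tested (16842). Values of log2(TPM + 1) from all 12 libraries were fitted with 6 group means in limma 3.58.1 (R 4.3.3), with a variance trend on mean expression. Contrasts were induced against untreated in each line, the difference between each knockdown line's change and the shCTRL change, the difference between the shRCOR2 and shRCOR1 changes, and each untreated knockdown line against untreated shCTRL. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested; unadjusted counts use p below 0.05 as well. Changes are log2 differences with their standard error (SE), and TPM are means with their standard deviation (SD). Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Data of this layout were simulated with 200 genes changed by 0.5, 1 or 2 (log2). The within-line contrast recovered 11.9%, 62.7% and 93.9% of these changes with 6 false calls by limma. The contrast between lines recovered 0%, 25.4% and 69.7% with 0 false calls. Noise was drawn independently for each library, and changes were planted only in genes with a mean above about 5 TPM. The simulation lacks the deviations that groups share by replicate number, described next. Its rates therefore do not carry over to the measured data or to sparser genes.

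The deviation of replicate 1 from its group mean correlated across genes between all 15 pairs of groups, with coefficients of 0.37 to 0.75, and the first principal component (31.9% of the variance) separated replicate 1 from replicate 2. The replicate numbers therefore pair the samples across groups, and every result was also computed with the replicate number as a block. The comparisons, the unblocked test, the lists and the named-gene rule were fixed before the data were examined, so the unblocked values come first, and blocked ones are added beside most results given here where they change a call or a count by more than 1.5 times.

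The 23 gene lists, with 703 members, cover CoREST complex and partners, adrenergic identity transcription factors, mesenchymal identity, catecholamine synthesis and storage, neuronal cytoskeleton and synapse, Schwann cell and neural crest markers, neurotrophin and receptor tyrosine kinase signalling, Notch and Hedgehog and Wnt targets, MYC targets and ribosome biogenesis, G2/M and mitosis, S phase and E2F targets, p53 targets, replication-dependent histones, integrated stress and unfolded protein response, hypoxia and glycolysis, cholesterol synthesis and uptake, nuclear-encoded respiratory chain, mitochondrially encoded proteins, immediate early genes, type I interferon response, and markers of epithelial cells, of leukocytes and of fibroblasts and endothelium. They were tested against the other genes with camera in limma at a preset correlation of 0.01, adjusted over the 23 lists, and again with the correlation estimated from the data. The rotation test fry, whose p-values shift slightly with the order of the groups in the design, was a further alternative. Named genes are, besides the RCOR family, the 8 largest rises and 8 largest falls in each line and the 5 largest of each in each difference, among called genes that reach a mean TPM of 5 in a group, have a symbol at 1 locus, and have both induced libraries on the same side of both untreated ones. Each list adds its 4 called genes with the largest change, or its 2 most expressed genes where none is called. A few genes that meet these rules are not reported here. Genes outside these rules are named only as ones chosen after their values were seen.

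Alternatives were a pseudocount of 0.1, FPKM, median-of-ratios scaling, quantile normalization, TPM without mitochondrial genes, no filter, a mean TPM of at least 5, no variance trend, the replicate block, a fit of only the groups compared, a minimum change of 1 (log2), and each library left out in turn. Groups of 2 are too small for a test of outlying samples or for recounting over other splits of the samples, and the 2 untreated and 2 induced shCTRL libraries serve both differences from shCTRL. Further tests on 7-base words in 3′ UTRs used 12637 genes with at least 50 bases of 3′ UTR and 16243 words present in at least 50 genes. For each word, the log2 change was regressed on its presence with UTR length and GC content as covariates, and words were adjusted by Bonferroni. A word planted in 938 genes with a change of −0.4 ranked 1, and 1 word passed in shuffled data.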

Results

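Expression of the coding and non-coding genes was measured in TPM in Kelly cells with an inducible shRNA against RCOR1, against RCOR2 or with a control shRNA. There were 2 untreated and 2 induced libraries per line, and 12 in all. Read totals are not in the files; by the ratio of coverage to FPKM the libraries spread from 1 to 2.16 times the shallowest one. Across the 16842 genes tested, the first 2 principal components held 31.9% and 27.9% of the variance.

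**Figure D1:**
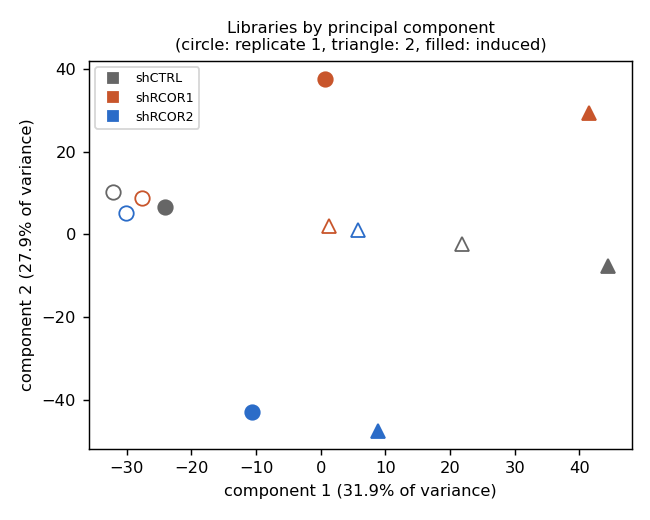
Principal components of log2(TPM + 1) over the 16842 tested genes, 1 point per library. Colours mark the line, filled symbols the induced libraries, and circles or triangles the replicate number. The first component (31.9%) parts replicate 1 from replicate 2, and the second holds 27.9%.

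The targeted transcripts were read first, to see how far each shRNA lowered its own target and its relatives. RCOR2 (ENSG00000167771.6, chromosome 11, 63911230 to 63917164, GRCh38/hg38) fell from 52.7 ± 3.91 TPM (SD, n = 2) in untreated shRCOR2 cells to 19.1 ± 1.94 TPM (n = 2) in induced ones. The libraries gave 55.4 and 49.9 TPM untreated and 17.7 and 20.5 TPM induced, a change of −1.42 ± 0.11 (SE; limma adjusted p = 0.000403). RCOR1 (ENSG00000089902.10, chromosome 14, 102592649 to 102730561) was a sparser transcript and fell in induced shRCOR1 cells from 8.70 ± 0.539 to 4.93 ± 0.191 TPM (n = 2 each). Its libraries gave 8.32 and 9.08 TPM untreated and 4.80 and 5.07 TPM induced, a change of −0.71 ± 0.12 (limma adjusted p = 0.0109). The RCOR2 transcript fell in the shRCOR1 line as well, from 50.9 ± 0.618 to 26.1 ± 0.214 TPM (51.4 and 50.5 untreated, 26.0 and 26.3 induced), by 0.94 ± 0.11 (limma adjusted p = 0.00278). RCOR1 was not called in the shRCOR2 line (0.01 ± 0.12, limma adjusted p = 0.983), and RCOR3 (chromosome 1, 211258377 to 211316385) was not called in either line (0.16 ± 0.21 and −0.15 ± 0.21; limma adjusted p = 0.661 and 0.736). In shCTRL cells, RCOR2 went from 54.6 and 50.2 to 49.7 and 42.7 TPM and RCOR1 from a mean of 9.82 to 8.99 TPM, and neither was called (−0.18 ± 0.11 and −0.11 ± 0.12; limma adjusted p = 0.957 and 0.989).

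Relative to the shCTRL change, RCOR2 fell by 1.24 ± 0.16 in the shRCOR2 line (limma adjusted p = 0.0129). For RCOR1 in the shRCOR1 line the difference was −0.60 ± 0.17, called with the replicate block (limma adjusted p = 0.0452) and not without it (0.158). For RCOR2 in the shRCOR1 line it was −0.75 ± 0.16, again called with the block (limma adjusted p = 0.0163) and not without it (0.069). The RCOR1 call in its own line ended when any 1 of that line's 4 libraries was left out, in fits that leave 1 library in a group. The RCOR1 fall itself ran from −0.77 to −0.65 over the libraries left out in turn, against −0.71 with all of them.

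**Figure D2:**
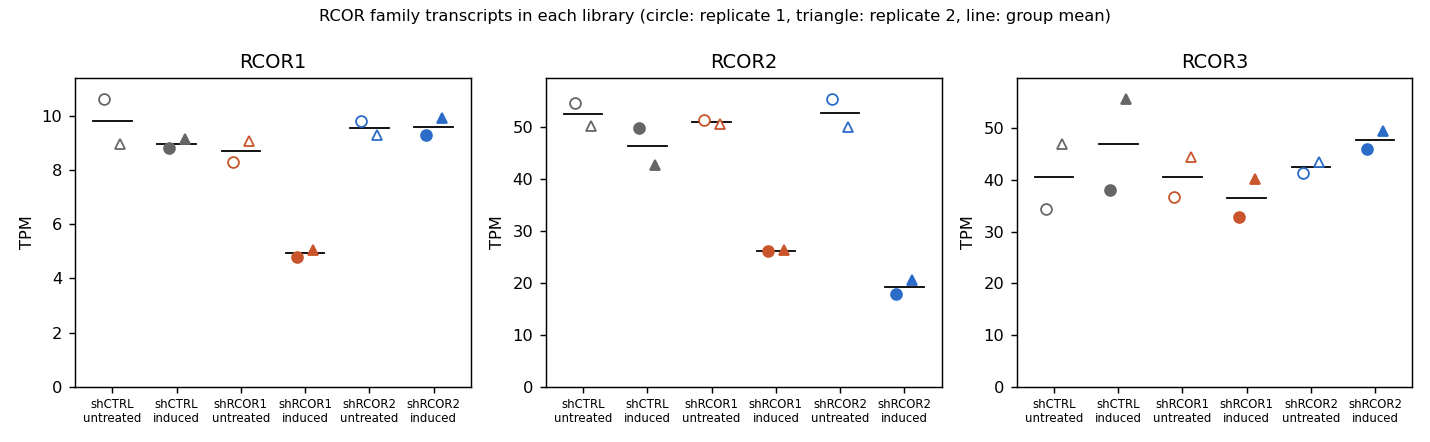
TPM of RCOR1, RCOR2 and RCOR3 in each of the 12 libraries (circles replicate 1, triangles replicate 2, lines group means). RCOR2 lies at 17.7 and 20.5 TPM in induced shRCOR2 cells and at 26.0 and 26.3 TPM in induced shRCOR1 cells, below every untreated library.

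Induced against untreated shRCOR2 cells show which transcripts changed with doxycycline and the shRNA against RCOR2 together. Among the falls was STMN1, which encodes the microtubule regulator stathmin: from 835 and 692 TPM to 127 and 108 TPM (n = 2 each; −2.69 ± 0.29, limma adjusted p = 0.0014). TXNRD1, for a cytosolic thioredoxin reductase, fell from 205 ± 24.7 to 31.7 ± 1.26 TPM (−2.65 ± 0.13), and LDHA, for lactate dehydrogenase, from 724 ± 26.4 to 170 ± 3.24 TPM (−2.08 ± 0.26). MYCN, the amplified driver of this tumour type, fell from 2848 ± 242 to 1156 ± 161 TPM (−1.31 ± 0.31, limma adjusted p = 0.0269). ACTA2, which encodes smooth muscle actin, rose from 1.79 ± 0.276 to 18.0 ± 1.22 TPM (2.77 ± 0.40), and the Wnt inhibitor DKK1 rose from 31.0 ± 4.74 to 147 ± 17.6 TPM (2.21 ± 0.23). Also among the largest rises were VIP (2.54 ± 0.23), IP6K3 (2.32 ± 0.43), the pseudogene ASNSP1 (2.31 ± 0.51), PLXNB3 (2.30 ± 0.29), CHAC1 (2.28 ± 0.42) and PTPRR (from 1.48 ± 0.260 to 10.5 ± 2.89 TPM). The other large falls were in ANP32E (−2.26 ± 0.19), COX7A2L (−2.24 ± 0.12), MZT1 (−1.99 ± 0.15), HSPB1 (−1.96 ± 0.14) and PPT1 (−1.89 ± 0.09).

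In total, 1316 genes rose and 1090 fell in the shRCOR2 line, 230 and 246 of them by at least 2-fold; with the replicate block 3611 rose and 2489 fell. Rises made up 54.7% of the calls with TPM and 68.2% with FPKM (2069 rises and 966 falls), but falls outnumbered rises with median-of-ratios scaling (45.7% rises, 1079 against 1283) and quantile normalization (49.5%). FPKM moved the median of all genes by 0.03 and those 2 scalings by −0.07 and −0.06, which moves the share too. Leaving out untreated replicate 1 or 2 of this line gave 744 or 583 called genes, of which 47.0% or 39.1% were rises, and leaving out induced replicate 1 or 2 gave 493 or 654, with 37.5% or 43.4% rises.

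Several cell cycle arrest and death genes that p53 drives rose in shRCOR2 cells. CDKN1A, for the kinase inhibitor p21, went from 40.3 ± 6.87 to 129 ± 10.8 TPM (1.66 ± 0.17), TP53I3 changed by 1.83 ± 0.33, ZMAT3 by 1.54 ± 0.20 and the death gene BBC3 by 1.35 ± 0.21. Of 24 measured p53 targets 13 rose and 1 fell, and 17 rose and 1 fell adjusted over the list alone; camera in limma gave adjusted p = 2.37e-08, and adjusted p = 0.202 with an estimated correlation. Some mitotic genes fell: BIRC5 went from 159 ± 31.8 to 42.4 ± 7.08 TPM (−1.88 ± 0.38), KIF11 changed by −1.05 ± 0.25, TOP2A by −1.04 ± 0.22 and the proliferation marker MKI67 by −0.96 ± 0.22. Of 35 measured G2/M genes 8 fell (34 with the replicate block), and 17 fell adjusted over the list alone; camera gave adjusted p = 4.65e-11, and adjusted p = 0.754 with an estimated correlation. The G2/M median was −0.80 here and −0.37 in shCTRL cells, and limma called 0 of the 35 in the difference from shCTRL (5 lower with the block). The S phase list had 1 fall of 39 (8 with the block), the helicase gene MCM4 (−1.85 ± 0.33), and 1 adjusted over the list alone. Camera for this list gave adjusted p = 0.000122, and adjusted p = 0.908 with an estimated correlation. The S phase median was −0.39 in shRCOR2, −0.28 in shRCOR1 and −0.43 in shCTRL cells, and its differences from shCTRL had camera adjusted p = 0.357 and 0.943 in limma. Replication-dependent histone genes that rose were led by H4C14 (1.65 ± 0.30), H4C3 (1.38 ± 0.18), H4C8 (1.36 ± 0.34) and H3C10 (1.20 ± 0.28). Of 25 measured histone genes 8 rose (14 with the block), and 9 rose adjusted over the list alone. Tested by camera, the list had adjusted p = 3.72e-06, and adjusted p = 0.648 with an estimated correlation. The histone median was 0.74 here and 0.28 in shCTRL cells.

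Some metabolic genes fell in the same line. Besides LDHA, the glycolysis and hypoxia genes PDK1 (−1.21 ± 0.20), CA12 (−1.15 ± 0.17) and ENO1 (−1.11 ± 0.23, from 2107 ± 173 to 983 ± 150 TPM) fell, and 11 of 34 did so (25, with 1 rise, with the block), or 15 adjusted over the list alone. Against other genes, camera gave adjusted p = 1.09e-09, and adjusted p = 0.202 with an estimated correlation. Of the sterol genes, MSMO1 fell by 1.20 ± 0.29 and INSIG1 by 1.15 ± 0.24. In the cholesterol list 12 of 25 fell (18, with 2 rises, with the block), or 17 adjusted over the list alone. The camera test gave adjusted p = 1.29e-08, and adjusted p = 0.648 with an estimated correlation. Ribosome biogenesis and MYC target genes that fell included the nucleolar helicase gene DDX21 (152 ± 2.71 to 44.6 ± 2.41 TPM, −1.75 ± 0.10), TSR1 (−0.98 ± 0.14), NIP7 (−0.98 ± 0.14) and the mitochondrial chaperone gene HSPD1 (−0.78 ± 0.12). In the MYC list 11 of 45 fell (24 with the block), and 11 adjusted over the list alone. Camera for this list gave adjusted p = 5.06e-09, and adjusted p = 0.754 with an estimated correlation.

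Identity genes moved both ways in shRCOR2 cells. Besides MYCN, the adrenergic factor LMO3 fell (−0.98 ± 0.16) while NEUROD1 rose (0.58 ± 0.15). Of 34 adrenergic factors 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.129), and the list median, −0.05, changed sign with FPKM; the block gave 3 rises and 9 falls. The dopamine-making enzyme gene DDC fell from 699 ± 161 to 206 ± 92.9 TPM (−1.81 ± 0.27), the vesicle transporter gene SLC18A2 by 1.41 ± 0.30 and CHGA by 0.98 ± 0.28, while SCG2 rose (0.96 ± 0.22); the catecholamine list had 2 rises and 3 falls of 19 (4 and 6 with the block; camera adjusted p = 0.29). Neuronal genes that fell included UCHL1 (943 ± 23.0 to 280 ± 0.113 TPM, −1.75 ± 0.20), CPLX2 (−1.20 ± 0.25) and CNTNAP2 (−1.17 ± 0.22), while the adhesion gene L1CAM rose (0.97 ± 0.18). The neuronal list had 4 rises and 5 falls of 50 (11 and 10 with the block), with a median of 0.13 and a camera test that pointed down (adjusted p = 0.588). All 5 of these falls hold a 3′ UTR word that may be a seed match of this shRNA, as described below. The Schwann cell list had 1 rise and 5 falls of 11 (SOX2 −1.53 ± 0.35, GFRA3 −1.15 ± 0.32, EDNRB −0.99 ± 0.26); its camera adjusted p was 0.0691 in limma, and 0.0497 with the replicate block (adjusted p = 0.566 with an estimated correlation and the block). For mesenchymal identity, with IRF2 up (0.61 ± 0.15) and FOSL2 (−0.79 ± 0.12) and SPARC (−0.69 ± 0.17) down of 34 genes (4 up and 10 down with the block), the camera adjusted p was 0.172 in limma and 0.0497 with the block (adjusted p = 0.782 with an estimated correlation and the block).

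Of the remaining lists in this line, CoREST partners had 3 falls of 19: RCOR2, the deacetylase gene HDAC2 (−1.16 ± 0.12) and CTBP2 (−0.67 ± 0.12); its median was 0.11 and its test pointed down (camera adjusted p = 0.404). Stress response genes split, with 3 rises and 3 falls of 29 (13 rises and 6 falls with the block, camera adjusted p = 0.674). CHAC1 and XBP1 (0.78 ± 0.16) were among the rises, and SLC7A5 (−1.45 ± 0.20) and HSPA5 (−0.78 ± 0.18) among the falls. In shCTRL cells 0 of the 29 were called, but the list median was 0.75. XBP1 went there from 109 and 126 to 163 and 238 TPM, and CHAC1 as given above. The difference from shCTRL had 0 of the 29 called higher and 3 lower, so the rises are not particular to shRCOR2. The Notch, Hedgehog and Wnt list had DKK1 up and DLL3 (−1.17 ± 0.15), NRARP (−0.81 ± 0.22) and GLI2 (−0.72 ± 0.17) among 4 falls of 23 (2 rises and 5 falls with the block; camera adjusted p = 0.172). Respiratory chain genes COX6C (−1.41 ± 0.17), UQCRC2 (−0.87 ± 0.10) and UQCRFS1 (−0.61 ± 0.11) fell, 3 of 42 (1 rise and 11 falls with the block). Its camera adjusted p was 0.129 in limma and 0.0334 with the block (adjusted p = 0.566 with an estimated correlation and the block), and the list median, −0.02, changed sign with FPKM and with quantile normalization. GFRA3, SPRY1 (−0.78 ± 0.20) and SPRED1 (−0.67 ± 0.16) were the 3 falls of 27 in the neurotrophin and kinase list, whose median was 0.10 with a test pointing down (camera adjusted p = 0.984); the block gave 6 rises and 4 falls. IFI35 (2.55 ± 0.655 to 6.55 ± 0.565 TPM) and IRF7 (0.70 ± 0.13) were the 2 rises of 18 interferon genes (3 rises and 3 falls with the block; camera adjusted p = 0.446), and ACTA2 and KDR (1.82 ± 0.23) the 2 rises of 12 fibroblast and endothelial markers (2 rises and 1 fall with the block; camera adjusted p = 0.655). No gene was called by limma among 5 epithelial markers, 3 leukocyte markers, 21 immediate early genes or 13 mitochondrially encoded ones (camera adjusted p = 0.599, 0.465, 0.984 and 0.984). With the block limma called 2 rises, 1 fall, 2 rises, and 5 rises and 2 falls in these lists.

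Induced against untreated shRCOR1 cells show which transcripts changed with the shRNA against RCOR1. The protease inhibitor gene TFPI2 rose from 0.311 ± 0.175 to 276 ± 38.6 TPM (n = 2 each; 7.72 ± 0.17, limma adjusted p = 2.68e-07). DKK1 rose from 31.1 ± 2.86 to 425 ± 25.9 TPM (3.73 ± 0.23), and the neuropeptide precursor gene VGF from 16.9 ± 0.791 to 353 ± 178 TPM (4.21 ± 0.49). The calcium sensor gene NCALD fell from 33.7 ± 0.0548 to 5.32 ± 0.155 TPM (−2.46 ± 0.09). The heat shock gene HSPA6 (5.05 ± 0.77), IL11 (3.87 ± 0.56), CGA (3.84 ± 0.57), the kinase pathway inhibitor gene SPRY4 (3.47 ± 0.46) and CDC42EP1 (3.34 ± 0.67) were the other large rises. Further large falls were in INSM2 (−2.42 ± 0.37, from 363 ± 55.1 to 72.6 ± 40.7 TPM), TG (−1.99 ± 0.51), the hypoxia factor gene EPAS1 (−1.91 ± 0.23), AL133163.3 (−1.81 ± 0.17), IFI6 (−1.79 ± 0.24) and TMEM183B (−1.75 ± 0.15).

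In this line 838 genes rose and 613 fell, 309 and 139 of them by at least 2-fold; with the replicate block 2590 rose and 2030 fell. Rises made up 57.8% of the calls, and 46.6% once mitochondrial genes were left out of TPM (566 rises and 649 falls), which moved the median of all genes by −0.04. Leaving out untreated replicate 1 or 2 of this line gave 326 or 387 called genes, and leaving out induced replicate 1 or 2 gave 694 or 431.

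Stress response genes rose in shRCOR1 cells and leaned the same way in shCTRL cells. SESN2 went from 22.1 ± 5.08 to 123 ± 28.3 TPM (2.43 ± 0.53), TRIB3 changed by 2.27 ± 0.59, CHAC1 by 2.18 ± 0.42 and ATF3 by 2.15 ± 0.34. Of 29 integrated stress genes 15 rose (25 with the block), and 23 rose adjusted over the list alone; camera in limma gave adjusted p = 2.88e-11, and adjusted p = 0.509 with an estimated correlation. The list median was 1.02 here and 0.75 in shCTRL cells, and limma called 0 of the 29 in the difference from shCTRL (3 higher and 1 lower with the block). Immediate early genes that rose included ATF3, NR4A1 at 1.83 ± 0.31, KLF6 at 1.67 ± 0.18 and DUSP2 at 1.56 ± 0.38, and were 7 of 21 (13 with the block), or 13 adjusted over the list alone. Tested by camera, the list had adjusted p = 1.13e-06, and adjusted p = 0.509 with an estimated correlation. Besides SPRY4, the phosphatase genes DUSP4, DUSP5 and DUSP6 rose: DUSP4 from 5.27 ± 0.540 to 56.9 ± 1.59 TPM (3.21 ± 0.18), DUSP5 by 2.89 ± 0.26 and DUSP6 by 2.80 ± 0.34. The neurotrophin and kinase list had 4 rises and 1 fall of 27 (11 and 3 with the block; 8 and 3 adjusted over the list alone; camera adjusted p = 0.0134; adjusted p = 0.509 with an estimated correlation). Hypoxia genes that rose included PFKFB3 (1.99 ± 0.32), VEGFA (1.25 ± 0.28, 87.8 ± 10.6 to 212 ± 39.5 TPM), ADM (0.90 ± 0.21) and HK2 (0.72 ± 0.18). There were 8 rises and 0 falls of 34 in that list by limma, or 16 rises and 7 falls with the block, and 9 adjusted over the list alone. Against other genes, camera gave adjusted p = 0.022, and adjusted p = 0.615 with an estimated correlation. In shCTRL cells VEGFA went from 60.6 and 96.2 to 121.5 and 192 TPM, and HK2 from 50.9 and 59.0 to 59.0 and 72.6 TPM. PFKFB3 and ADM lay lower in both induced shCTRL libraries than in both untreated ones. Limma called 0 of the 34 in shCTRL (1 rise with the block). In the difference between shRCOR1 and shCTRL it called 1 higher (8 with the block). DKK1, HES4 (1.43 ± 0.29), HES1 (1.21 ± 0.24) and the cyclin gene CCND1 (1.08 ± 0.21) were the 4 rises of 23 in the Notch, Hedgehog and Wnt list (5 rises and 1 fall with the block), and 4 adjusted over the list alone. The camera test gave adjusted p = 0.0411, and adjusted p = 0.615 with an estimated correlation.

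Several adrenergic identity factors fell in shRCOR1 cells. Next to INSM2, EYA1 went from 56.7 ± 3.68 to 17.3 ± 4.31 TPM (−1.68 ± 0.21), TFAP2B changed by −1.43 ± 0.22 and LMO1 by −1.38 ± 0.20. Of 34 factors 1 rose and 11 fell (4 and 14 with the block), and 4 rose and 13 fell adjusted over the list alone. Of the 11 falls, 8 hold a 3′ UTR word that may be a seed match of the RCOR1 shRNA, as described below. Camera for this list gave adjusted p = 7.15e-05, and adjusted p = 0.236 with an estimated correlation. Mesenchymal identity genes that rose were led by FOSL2 (10.4 ± 0.559 to 51.8 ± 4.20 TPM, 2.21 ± 0.12), ID1 (1.92 ± 0.44), MAFF (1.82 ± 0.22) and TGFBI (1.76 ± 0.43). That list had 5 rises and 1 fall of 34 (16 and 2 with the block), and 12 and 1 adjusted over the list alone. Tested by camera, the list had adjusted p = 0.00211, and adjusted p = 0.653 with an estimated correlation. The granin gene CHGA fell from 3237 ± 49.5 to 1121 ± 298 TPM, MAOA by 1.19 ± 0.23 and DDC by 1.14 ± 0.27, while SCG2 rose (2.22 ± 0.22). The catecholamine list had 1 rise and 5 falls of 19 (3 and 8 with the block), and 2 and 7 adjusted over the list alone. Against other genes, camera gave adjusted p = 0.0193, and adjusted p = 0.509 with an estimated correlation. The cyclin gene CCNA2 (−1.49 ± 0.35), ASPM (−0.80 ± 0.16) and CENPF (−0.61 ± 0.15) were the 3 falls of 35 G2/M genes (32 with the block), with 9 adjusted over the list alone. The camera test gave adjusted p = 9.93e-11, and adjusted p = 0.615 with an estimated correlation. The S phase list had 1 fall of 39 (1 rise and 6 falls with the block; camera adjusted p = 0.00634; adjusted p = 0.823 with an estimated correlation).

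SDHC (−1.08 ± 0.12), UQCRFS1 (−0.74 ± 0.11), NDUFV2 (−0.66 ± 0.14) and NDUFA10 (−0.51 ± 0.13) were the 4 falls of 42 respiratory chain genes in this line (18 with the block), and 4 adjusted over the list alone. Camera for this list gave adjusted p = 0.000328, and adjusted p = 0.653 with an estimated correlation. EPCAM rose from 0.298 ± 0.0168 to 3.65 ± 0.67 TPM (1.83 ± 0.33), the 1 call of 5 epithelial markers (3 rises with the block), with 3 rises adjusted over the list alone. Tested by camera, the list had adjusted p = 0.0411, and adjusted p = 0.615 with an estimated correlation. H4C3 rose (0.83 ± 0.18) and H2AC13 fell (−0.69 ± 0.15) of 25 histone genes (2 and 6 with the block), with 2 and 5 adjusted over the list alone and a camera test that pointed down (adjusted p = 0.0411; adjusted p = 0.695 with an estimated correlation). CoREST partners had SNAI1 up (0.78 ± 0.15) and 3 down, RCOR1 and RCOR2 among them, of 19 (2 and 5 with the block; camera adjusted p = 0.0641). LSS (−1.22 ± 0.29) and STARD4 (−0.86 ± 0.18) were among 3 falls, with 1 rise, of 25 cholesterol genes (6 falls and 1 rise with the block), with a median of 0.01 and a test pointing down (camera adjusted p = 0.216). BBC3 (2.23 ± 0.21), CDKN1A (0.96 ± 0.17) and PLK3 (0.84 ± 0.17) were among 4 rises, and DDB2 (−0.83 ± 0.14) among 2 falls, of 24 p53 targets (6 rises and 7 falls with the block; camera adjusted p = 0.893). Neuronal genes had 5 rises and 3 falls of 50 (9 and 11 with the block), among them STMN4 up (2.38 ± 0.18), ELAVL4 up (1.38 ± 0.28) and CNTNAP2 down (−1.64 ± 0.22; camera adjusted p = 0.629). IFI6, IRF7 (−0.78 ± 0.13) and IFIT5 (−0.74 ± 0.13) fell and ISG20 rose (1.01 ± 0.22) of 18 interferon genes (5 falls and 1 rise with the block; camera adjusted p = 0.114). HSPD1 (0.51 ± 0.12) and DDX21 (0.44 ± 0.10) rose and CAD fell (−0.58 ± 0.10) of 45 MYC targets (6 rises and 2 falls with the block; camera adjusted p = 0.632). MBP (0.96 ± 0.18) and NES (0.85 ± 0.12) were the 2 rises of 11 Schwann cell markers, whose median was −0.10 with a test pointing up (2 rises and 1 fall with the block; camera adjusted p = 0.632), and VWF (0.77 ± 0.19) the 1 rise of 12 fibroblast and endothelial markers (1 rise and 1 fall with the block; camera adjusted p = 0.893). Among 13 mitochondrially encoded genes and 3 leukocyte markers 0 were called by limma (camera adjusted p = 0.122 and 0.767). With the block, 5 mitochondrially encoded genes fell and their camera adjusted p was 0.0121 (adjusted p = 0.479 with an estimated correlation and the block).

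**Figure D3:**
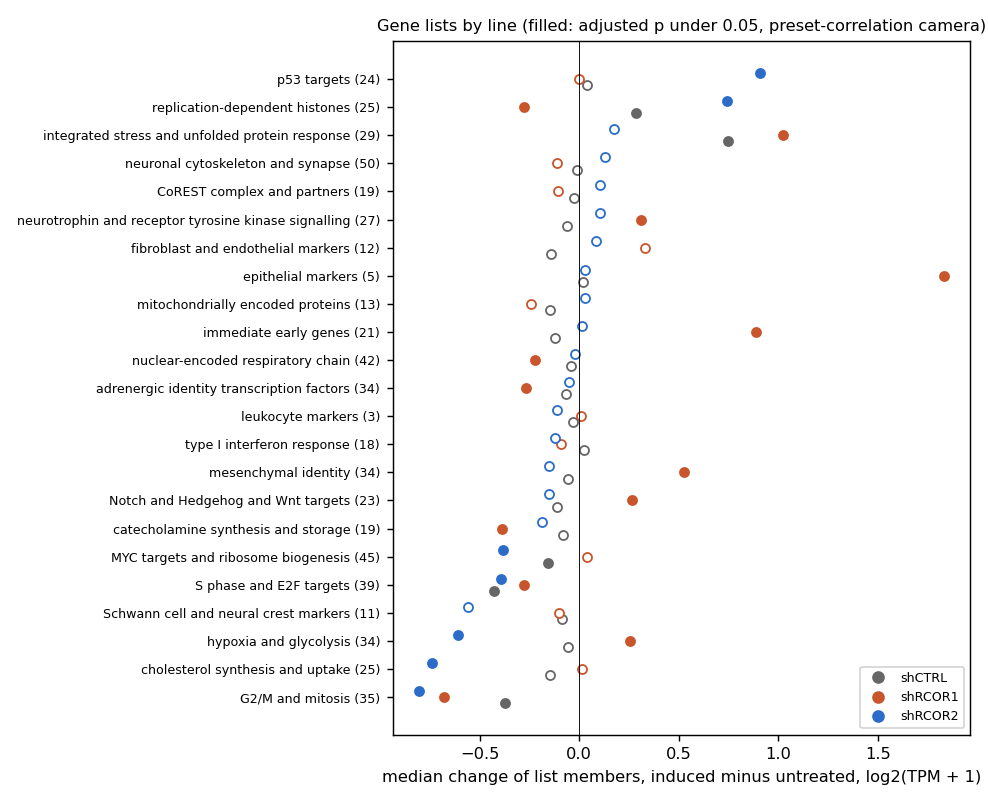
Median log2 change of each of the 23 gene lists in the 3 lines, induced minus untreated; filled points have a camera adjusted p below 0.05 at the preset correlation of 0.01. The p53 list is filled in shRCOR2, the histone list in all 3 lines (above 0 in shRCOR2 and shCTRL, below in shRCOR1), the integrated stress list in shRCOR1 and shCTRL, and 0 lists pass in any line with an estimated correlation.

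Induced against untreated shCTRL cells show what doxycycline and a control shRNA changed. ATF4, the transcription factor of the amino acid response, went from 466 ± 2.85 to 674 ± 50.2 TPM (n = 2 each; 0.53 ± 0.12, limma adjusted p = 0.791). The serine synthesis gene PHGDH went from 410 ± 34.2 to 612 ± 63.4 TPM (0.58 ± 0.12), and TWIST1 from 156 ± 25.9 to 103 ± 9.27 TPM (−0.59 ± 0.12), with limma adjusted p = 0.782 for both. No gene was called by limma (0 of 16842; smallest adjusted p 0.441), 938 had an unadjusted p below 0.05 where chance gives 842, and with the replicate block 2642 did and limma called 5 rises and 5 falls. In the integrated stress list, 12 of 29 genes rose adjusted over the list alone and the median was 0.75 (camera adjusted p = 2.71e-23; adjusted p = 0.617 with an estimated correlation). Lists for G2/M, S phase and MYC targets lay below the other genes and histones above them (limma's camera adjusted p = 2.77e-07, 8.12e-07, 0.00125 and 2.64e-05; adjusted p = 0.954 with an estimated correlation for each). The 3 lower calls ended without untreated shCTRL replicate 1, and fewer lists lay below without induced replicate 2. Such a fit sets 1 replicate number against both, so the difference between replicate numbers enters it. With the replicate block, which takes that difference out, the G2/M, S phase and MYC lists stayed lower (limma's camera adjusted p = 5.02e-15, 2.93e-08 and 0.000247). With an estimated correlation and the block, camera gave adjusted p = 0.916 for each.

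Taking the shCTRL change away from the shRCOR2 change separates the RCOR2 shRNA from doxycycline. The secreted neuropeptide gene VIP differed by 2.62 ± 0.32 (limma adjusted p = 0.0121), PLXNB3 by 2.41 ± 0.41, the mitochondrial tRNA gene MT-TD by 2.17 ± 0.37, DKK1 by 2.12 ± 0.32 and PTPRR by 2.04 ± 0.30. In the other direction, TXNRD1 differed by −2.62 ± 0.18 (limma adjusted p = 0.00182), STMN1 by −2.46 ± 0.41, COX7A2L by −2.44 ± 0.17, the amino acid transporter gene SLC7A5 by −2.28 ± 0.29 and ANP32E by −1.98 ± 0.27. MYCN differed by −1.06 ± 0.44 and was not called (limma adjusted p = 0.259). Called differences numbered 352, of which 150 were higher and 202 lower; with the block they were 1504 and 977. Leaving out 1 library gave 19 to 321 (19 without untreated shRCOR2 replicate 2), and a fit of only the groups compared 8. The higher share was 42.6%, against 27.8% with median-of-ratios scaling (104 and 270), 27.3% with quantile normalization (129 and 343) and 60.6% with the block. Those scalings moved the median of all genes by −0.09 and −0.07, which moves the share too.

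Of the lists, hypoxia genes had 2 differences below shCTRL (15 with the block) and 8 adjusted over the list alone. Against other genes, camera gave adjusted p = 2.07e-09, and adjusted p = 0.239 with an estimated correlation. The p53 targets had 4 above (12 with the block), and 14 above and 1 below adjusted over the list alone. The camera test gave adjusted p = 9.38e-07, and adjusted p = 0.298 with an estimated correlation. Integrated stress genes had 3 below (6 with the block), and 6 adjusted over the list alone. Camera for this list gave adjusted p = 1.59e-05, and adjusted p = 0.84 with an estimated correlation. MYC targets had 1 below (5 with the block), and 4 adjusted over the list alone. Tested by camera, the list had adjusted p = 3.69e-05, and adjusted p = 0.84 with an estimated correlation. Cholesterol, G2/M and histone genes had 0 called by limma, and 1 lower, 5 lower and 2 higher with the block (camera adjusted p = 9.38e-07, 3.81e-05 and 0.0119; adjusted p = 0.84 with an estimated correlation for each). Mesenchymal genes had a camera adjusted p of 0.135 in limma, and of 0.0285 with the block (adjusted p = 0.697 with an estimated correlation and the block).

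The same subtraction for the shRCOR1 line gave TFPI2 at 7.70 ± 0.24 (limma adjusted p = 5.41e-06), VGF at 4.36 ± 0.70, DKK1 at 3.64 ± 0.32, SPRY4 at 3.45 ± 0.66 and the phosphatase gene DUSP5 at 3.06 ± 0.37. Below shCTRL were NCALD (−2.11 ± 0.13, limma adjusted p = 0.000659), CHST2 (−1.70 ± 0.29), the glycolipid anchor gene PIGS (−1.67 ± 0.15) and POU2F2 (−1.67 ± 0.22). Called differences numbered 216, of which 142 were higher and 74 lower; with the block they were 1110 and 602. Leaving out 1 library gave 26 to 173 (26 and 27 without either untreated shRCOR1 library), and a fit of only the groups compared 18. The higher share was 65.7%, and 55.5% without mitochondrial genes in TPM (81 lower), where the median of all genes moved by −0.02. Adrenergic factors had 0 called by limma (1 higher and 9 lower with the block), and 1 higher and 10 lower adjusted over the list alone. Against other genes, camera gave adjusted p = 0.000195, and adjusted p = 0.277 with an estimated correlation. Immediate early genes had 1 higher (8 with the block), and 11 adjusted over the list alone. The camera test gave adjusted p = 3.29e-06, and adjusted p = 0.531 with an estimated correlation. The neurotrophin and kinase list had 4 higher, and 4 adjusted over the list alone. Camera for this list gave adjusted p = 0.00327, and adjusted p = 0.531 with an estimated correlation. Hypoxia genes had 1 higher (8 with the block), and 5 adjusted over the list alone. Tested by camera, the list had adjusted p = 0.0137, and adjusted p = 0.531 with an estimated correlation. Also apart from the other genes were the mesenchymal and Notch lists, above, with 2 and 1 genes higher (7 higher, and 3 higher and 1 lower, with the block). The catecholamine list lay below although its 1 called gene was higher (2 higher and 3 lower with the block), and the respiratory chain list lay below with 1 gene lower (6 with the block). These 4 lists, in that order, were tested the same way (limma's camera adjusted p = 0.00537, 0.0159, 0.0174 and 0.00117; adjusted p = 0.813, 0.531, 0.531 and 0.815 with an estimated correlation). Histone and G2/M genes lay below and MYC and epithelial genes above, with 0 called by limma and 1 histone gene lower adjusted over the list alone; the block gave 4 and 2 lower, then 2 higher and 1 lower, then 3 higher (camera adjusted p = 0.000149, 0.00117, 0.0286 and 0.041; adjusted p = 0.531, 0.815, 0.815 and 0.671 with an estimated correlation). Integrated stress, interferon and mitochondrially encoded genes had camera adjusted p of 0.0596, 0.0596 and 0.288 in limma, and of 0.0237, 0.0365 and 0.0398 with the block (adjusted p = 0.727, 0.538 and 0.551 with an estimated correlation and the block).

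The shRCOR2 and shRCOR1 changes were set against each other to see how far the paralogs' knockdowns overlap. PLAT, for tissue plasminogen activator, fell by 1.25 ± 0.22 in shRCOR2 cells and rose by 2.43 ± 0.22 in shRCOR1 cells, and the GTPase gene GEM fell by 1.23 ± 0.27 and rose by 2.35 ± 0.27. FOSL2 likewise fell by 0.79 ± 0.12 and rose by 2.21 ± 0.12, and SLC7A5 fell by 1.45 and rose by 1.68; GEM was chosen after its values were seen. Higher in shRCOR2 than in shRCOR1 cells were the changes of AC078950.1 (2.96 ± 0.47), TG (2.74 ± 0.73), FZD5 (2.60 ± 0.67), the developmental factor gene SHOX2 (2.54 ± 0.50) and UTRN (2.52 ± 0.27). Lower were those of TFPI2 (−7.77 ± 0.24), HSPA6 (−4.98 ± 1.09), CGA (−3.95 ± 0.81), VGF (−3.73 ± 0.70) and PLAT (−3.68 ± 0.31, limma adjusted p = 0.000873).

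In all, 875 changes were higher and 1005 lower in shRCOR2 than in shRCOR1; with the block they were 2642 and 2483. Higher changes were 46.5% of these with TPM and 59.9% with FPKM (1344 and 901). Within lines, 104 genes rose in both and 110 fell in both, where independent calls would give 65.5 and 39.7. Another 80 rose in shRCOR2 and fell in shRCOR1, and 96 did the reverse, where independence would give 47.9 and 54.2. With the replicate block 638 rose and 547 fell in both (555.3 and 300 if independent), and 408 and 446 moved in opposite ways (435.2 and 382.8), so the first opposite class was then smaller than independence gives. Across genes, which are not independent replicates, the changes had a Pearson coefficient of 0.08 and a Spearman coefficient of 0.07. With the shCTRL change the Pearson coefficient was 0.26 for each knockdown line. Changes shared with shCTRL were not taken out of these counts and coefficients. RCOR2 itself was called lower in both lines.

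Of the lists in this contrast, hypoxia genes had 13 changes lower in shRCOR2 (23 with the block), and 13 adjusted over the list alone. Against other genes, camera gave adjusted p = 2.6e-09, and adjusted p = 0.245 with an estimated correlation. Histone genes had 7 higher (13 with the block), and 12 adjusted over the list alone. The camera test gave adjusted p = 6.55e-06, and adjusted p = 0.563 with an estimated correlation. The p53 targets had 8 higher (12 higher and 1 lower with the block), and 11 higher and 1 lower adjusted over the list alone. By camera it had adjusted p = 6.38e-05, and adjusted p = 0.563 with an estimated correlation. MYC targets had 8 lower (15 with the block), and 9 adjusted over the list alone. For that list camera gave adjusted p = 7.85e-06, and adjusted p = 0.703 with an estimated correlation. Cholesterol genes had 4 lower (2 higher and 10 lower with the block), and 1 higher and 11 lower adjusted over the list alone. Set against other genes, its camera test gave adjusted p = 0.000799, and adjusted p = 0.645 with an estimated correlation. Integrated stress, Notch, immediate early, neurotrophin and mesenchymal lists had 8, 5, 4, 3 and 2 lower, and mesenchymal identity 1 higher too; with the block they had 11, 9, 7, 11 and 16 lower and 0, 1, 0, 3 and 2 higher (limma's camera adjusted p = 6.55e-06, 0.00281, 0.000239, 0.0183 and 0.000668; adjusted p = 0.609, 0.563, 0.563, 0.563 and 0.645 with an estimated correlation). Mitochondrially encoded genes had a camera adjusted p of 0.388 in limma, and of 0.0416 with the block (adjusted p = 0.581 with an estimated correlation and the block). Adrenergic factors had 7 higher and 2 lower (13 and 6 with the block), and 13 and 4 adjusted over the list alone. In camera it had adjusted p = 0.107, and adjusted p = 0.563 with an estimated correlation.

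**Figure D4:**
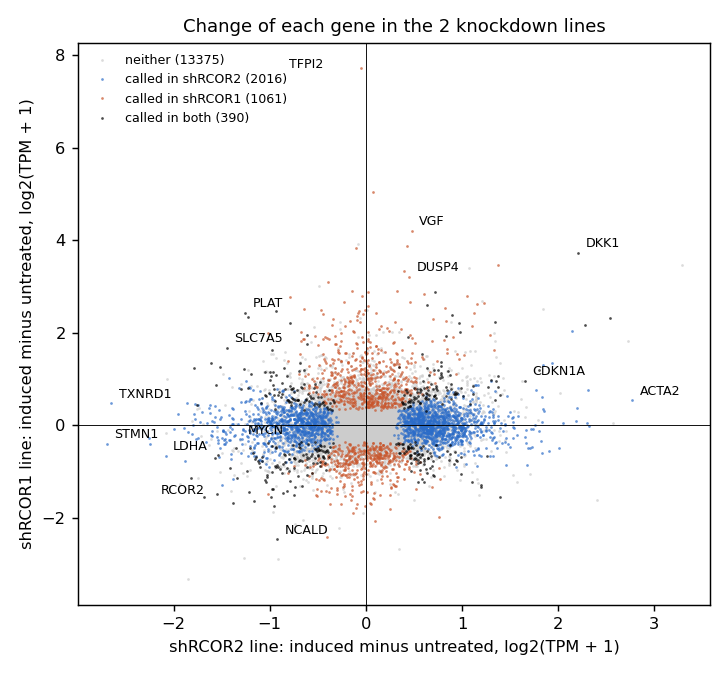
Log2 change, induced minus untreated, of each tested gene in the shRCOR2 line against the shRCOR1 line, 1 point per gene, with colours for genes called in both lines. The 214 genes called in the same direction and the 176 called in opposite directions lie around a cloud with a Pearson coefficient of 0.08.

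Untreated knockdown lines were compared with untreated shCTRL cells to see whether the lines differed before induction. RCOR2 lay at 52.7, 50.9 and 52.4 TPM and RCOR1 at 9.57, 8.70 and 9.82 TPM in untreated shRCOR2, shRCOR1 and shCTRL cells. No gene was called by limma in either comparison (0 and 0), and 123 and 114 had an unadjusted p below 0.05. With the replicate block limma also called 0 and 0, and 339 and 446 had an unadjusted p below 0.05, where chance gives 842.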

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

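The tests of shared reads, of mixed libraries and of the RCOR1 shRNA's seed, the grouping of overlapping words with its counts, and the 8-base word were chosen only after the results were seen; the correction for GC content and length was added after seeing the data, but its test was set out before its own result.

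Lines carrying different shRNAs changed differently, by tests of the differences themselves in limma. The shRCOR2 change differed from the shRCOR1 change for 1880 genes, among them TFPI2, VGF and PLAT. It differed from the shCTRL change for 352 genes, among them TXNRD1, STMN1 and VIP, and the shRCOR1 change differed from it for 216, among them NCALD and DUSP5. Among the 1880 are 176 genes, such as PLAT, SLC7A5 and FOSL2, that were called in opposite directions in shRCOR2 and shRCOR1. RCOR2 changed in shRCOR1 by −0.75 ± 0.16 relative to shCTRL (limma adjusted p = 0.069, and 0.0163 with the replicate block), and RCOR1 changed by 0.71 ± 0.17 more in shRCOR2 than in shRCOR1 (limma adjusted p = 0.034). The differences from shCTRL share their control libraries, which makes them resemble each other. In 50 simulations without any knockdown effect their median Pearson coefficient across genes was 0.495 and their median covariance 0.042. The measured values were 0.096 and 0.0217. The simulated changes hold noise alone, while the measured ones also hold changes of each line, which alter a Pearson coefficient. The simulated and measured coefficients therefore cannot be compared, and no conclusion is drawn from them. These simulations first used the unblocked spread and were redone with the blocked spread once the first result was seen.

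RCOR2 fell in the line with the RCOR1 shRNA. RCOR2 lost 24.8 TPM while RCOR1 had 8.70 TPM in untreated cells, but that value counts only reads placed on RCOR1. It therefore cannot exclude reads of RCOR1 that were placed on RCOR2. The longest stretch that the transcripts share, 15 bases, argues against reads that match both exactly. RNA of induced shRCOR2 cells in these libraries is excluded, since the 100 genes that fell most in shRCOR2 had a median of −0.11 in shRCOR1. A perfect match of the RCOR1 shRNA to RCOR2 over a full guide, set at 19 bases, is excluded. The longest stretch shared by RCOR1 and RCOR2 transcripts is 15 bases. Matches with mismatched bases were not searched for and stay open. A seed match, the pairing of a few guide bases with a 3′ UTR as a microRNA does, stays open: the RCOR2 3′ UTR holds 2 of the words that mark falling genes in the shRCOR1 line, CCAGAAA and TCCAGAA, and the merged word TCCAGAAA, which 2.53% of 3′ UTRs of similar length hold. Of the 918 genes with TCCAGAAA 116 were called lower and 21 higher, against 542 lower of all 12637. This excess restates the choice of the word from these same changes, and 53 of the 918 fell at least as much as RCOR2. Of 3′ UTRs of similar length, 32.0% hold at least 1 of the words. A response of RCOR2 to the loss of RCOR1, which was not tested apart from a seed match, may therefore also be the cause.

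Many genes fell in one knockdown line and not in the other. Trends on transcript GC content or length are excluded as the cause, since 97.0% of the falls called with the replicate block in shRCOR2 and 96.6% in shRCOR1 were still called after such trends were removed. Seed matches of each shRNA may lower part of the genes: ATGGCTA had the lowest of 16243 t values in shRCOR2 (−11.16, highest 5.82; 2.36 in shCTRL) and CCAGAAA the lowest in shRCOR1 (−14.06, highest 5.19; −1.28 in shCTRL), and the shRNA sequences were not available to match to them. ATGGCTA stood in 173 of the 1016 called falls with a searched 3′ UTR against 7.28% of other genes, among them STMN1, TXNRD1 and BIRC5, and CCAGAAA in 38.9% against 19.3%, among them NCALD, IFI6 and CCNA2, shares that restate the choice of the words from the same changes. At least 1 of the overlapping words stood in 56.3% of shRCOR2 and 69.7% of shRCOR1 falls. The shares were 22.2% and 50.1% of rises and 36.3% and 56.4% of all searched genes, and they too restate the choice of the words. In shRCOR2 such a word stood in 5 of 5 neuronal and 3 of 3 CoREST falls (RCOR2 included) but 0 of 4 Notch falls. In shRCOR1 it stood in 8 of 11 adrenergic, 4 of 4 respiratory chain and 3 of 3 interferon falls but 1 of 3 G2/M falls. LDHA, HSPB1 and MYCN in shRCOR2 and TG and LMO1 in shRCOR1 hold none of them, so loss of the targeted proteins stays open beside the seeds. Words that differ from the lowest one only in an end base, such as ATGGCTT in shRCOR2, were outside the set.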

How the results depend on the processing

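Removing genes that hold the lines' words and removing the trend on GC content and length were added after seeing the data. No named gene changed direction in any setting, but the majority direction of the calls did. Rises were 54.7% in shRCOR2, but 45.7% with median-of-ratios scaling, 49.5% with quantile normalization and 48.3% at a minimum change of 1; they were 57.8% in shRCOR1, but 46.6% without mitochondrial genes and 47.3% with the block and the trend removed. Higher changes were 42.6% in shRCOR2 minus shCTRL, but 52.2% with FPKM, 51.4% with no filter, 60.6% with the block and 65.0% induced against induced; in shRCOR2 minus shRCOR1 they were 46.5%, but 59.9% with FPKM, 50.9% without mitochondrial genes and 51.6% with the block. The scalings moved the median of all genes as well, by −0.07 (median-of-ratios) and −0.06 (quantile) in shRCOR2 and −0.04 (no mitochondrial genes) in shRCOR1. In shRCOR2 minus shRCOR1 they moved it by 0.06 (FPKM) and 0.03 (no mitochondrial genes). Such a common shift can move a share, but shifts of similar size went with unlike shares. Median-of-ratios scaling and leaving out mitochondrial genes multiply all values of a library by a common factor. The shift of the median does not show how such factors differ between replicates, so no cause besides scaling follows from it. In shRCOR1, median-of-ratios scaling and quantile normalization moved the median by −0.04 and −0.05 and left 56.8% and 55.4% rises. In shRCOR2 minus shCTRL, FPKM moved it by −0.0048 while the share rose to 52.2%. Of 182 named-gene results, 50 were no longer called without a filter (39169 genes tested), 46 in a fit of only the groups compared (fewer libraries), 17 with quantile normalization, 16 with median-of-ratios scaling, 14 without mitochondrial genes, 10 without the variance trend, 7 with a pseudocount of 0.1, 6 with FPKM and 0 with the replicate block. Over the same results with each library left out in turn, in fits of fewer libraries, 176 calls ended and 712 stayed in shRCOR2, and 248 ended and 688 stayed in shRCOR1. In the differences 53 ended and 67 stayed (shRCOR2 minus shCTRL), 41 and 79 (shRCOR1 minus shCTRL), and 33 and 87 (shRCOR2 minus shRCOR1). The RCOR1 fall in shRCOR1 was also −0.71 with only the groups compared, where its limma adjusted p was 0.0823. Depth sets no counting interval here, as the files used here hold no counts.

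With the replicate block, which takes out the difference between replicate numbers, limma called 6100 genes in shRCOR2, 4620 in shRCOR1, 10 in shCTRL, 2481 in shRCOR2 minus shCTRL, 1712 in shRCOR1 minus shCTRL and 5125 in shRCOR2 minus shRCOR1. With the GC and length trend removed as well, shRCOR2 and shRCOR1 gave 5960 and 4720. A minimum change of 1 (log2), stricter by construction, left 476, 448, 199 and 1002 genes in shRCOR2, shRCOR1, shRCOR2 minus shCTRL and shRCOR2 minus shRCOR1. Only the groups compared gave 585 in shRCOR1, 8 and 18 in the shRCOR2 and shRCOR1 differences from shCTRL, and 1 in untreated shRCOR2 against shCTRL. Induced against induced shCTRL cells, a contrast of fewer libraries, gave 2551 for shRCOR2 and 1515 for shRCOR1. Without the 4586 genes that hold its words, shRCOR2 gave 1608 genes (1090 rises and 518 falls, 67.8% rises). Without the 7128 genes that hold its own words, shRCOR1 gave 697 (462 and 235). Taking out that many genes lowers the counts by itself, so the drop does not measure the effect of seed matches. For the others the cause was not tested: no filter gave 6 genes in shCTRL, 350 in shRCOR1 minus shCTRL, and 5 and 2 in untreated shRCOR2 and shRCOR1 against shCTRL; quantile normalization gave 325 in shRCOR1 minus shCTRL, and TPM without mitochondrial genes 231 in shRCOR2 minus shCTRL. Genes called the same way in both lines numbered 214, and 9 among the differences from shCTRL.

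Lists past the threshold numbered 7, 13 and 5 in shRCOR2, shRCOR1 and shCTRL, and 7, 12 and 10 in the differences, in the order used above. With an estimated correlation all 6 contrasts gave 0 lists. With fry they gave 4, 6, 0, 2, 2 and 5.

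Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave 493 to 3036 genes in shRCOR2 (493 without shRCOR2 induced replicate 1) and 326 to 1900 in shRCOR1 (326 without shRCOR1 untreated replicate 1). It gave 0 to 0 in shCTRL, and 0 to 1 in untreated shRCOR2 and in untreated shRCOR1 against shCTRL (1 without either induced shCTRL library, and for shRCOR1 also without its untreated replicate 1). The RCOR1 fall ran from −0.77 to −0.65 and the RCOR2 fall from −1.52 to −1.32. Lists ran from 7 to 9, 7 to 13 and 4 to 7 in shRCOR2, shRCOR1 and shCTRL, with 7 in shRCOR1 without its induced replicate 2 (5 above and 2 below, from 7 and 6), and with 4 above and 0 below in shCTRL without its untreated replicate 1 (from 2 and 3), and from 5 to 9, 8 to 12 and 10 to 13 in the differences.

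For shRCOR2 minus shCTRL the range was 19 to 321. The counts were 92 and 92 without untreated and 174 and 172 without induced replicates 1 and 2 of shRCOR1, 23 and 19 without untreated and 27 and 39 without induced shRCOR2, and 51 and 36 without untreated shCTRL; without induced shCTRL replicate 2 it was 151. For shRCOR1 minus shCTRL the range was 26 to 173. Without untreated shRCOR1 it was 26 and 27, without induced shRCOR1 117 and 43, without untreated shRCOR2 82 and 81, without induced shRCOR2 66 and 66, without untreated shCTRL 41 and 41, and without induced shCTRL replicate 2 136. For shRCOR2 minus shRCOR1 the range was 693 to 2353, with 709 and 889 without untreated and 1132 and 1021 without induced shRCOR1, and 950 and 736 without untreated and 693 and 847 without induced shRCOR2.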

Other observations

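In shRCOR2 cells, 175 of 1935 measured long non-coding RNA genes were called higher and 22 lower, beside 1316 and 1090 of all 16842 genes, with a median of 0.20 (445 and 96 long non-coding genes with the replicate block), while in shRCOR1 cells 30 were higher and 34 lower, with a median of 0.01 (132 and 116 with the block). In limma's camera the long non-coding genes stood above the others in shRCOR2 (p = 0.0052 at the preset correlation and p = 0.554 with an estimated one). RN7SK (chromosome 6, 52995621 to 52995948, GRCh38/hg38), the RNA that holds back transcription elongation, rose in shRCOR1 cells by 2.65 ± 0.62 (n = 2 each, means of 16.6 and 107 TPM; limma adjusted p = 0.0345). It was not called in shRCOR2 (1.23 ± 0.62, limma adjusted p = 0.228) or shCTRL cells (0.65 ± 0.62, limma adjusted p = 0.987). These genes and the ones in the next paragraph, like the class tests and the depth and scaling tests on histones alone, were chosen after their values were seen.

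Mitochondrial ribosomal RNA took a smaller share of TPM in the induced library of 6 of 6 pairs, from 2.42% and 3.65% to 1.66% and 2.04% in shRCOR2, from 2.63% and 3.15% to 1.82% and 2.00% in shRCOR1, and from 2.89% and 3.11% to 2.35% and 2.11% in shCTRL. MT-RNR2 was not called (−0.60, −0.89 and −0.62; limma adjusted p = 0.131, 0.0546 and 0.871), though it was with the replicate block in shRCOR2 and shRCOR1 (limma adjusted p = 0.0128 and 0.00297). MT-RNR1 fell in shRCOR2 cells by 1.12 (log2; limma adjusted p = 0.0428) but was not called in shRCOR1 or shCTRL cells, where it lay higher in the induced ones (0.35 and 0.17; limma adjusted p = 0.56 and 0.993). A 5.8S ribosomal RNA gene on chromosome 21 (8256781 to 8256933), a sequence present at several loci so that its reads cannot be placed with certainty, rose from 89.8 ± 6.11 to 170 ± 1.48 TPM in shRCOR2 and from 102 ± 6.92 to 163 ± 2.30 TPM in shRCOR1 (limma adjusted p = 0.00237 and 0.010). It was not called in shCTRL (0.12 ± 0.11, limma adjusted p = 0.989).

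More long non-coding and replication-dependent histone genes were called higher than lower in shRCOR2 cells, though with an estimated correlation camera in limma gave p = 0.554 and 0.113, and histones also stood higher in shCTRL cells (median 0.28, camera adjusted p = 2.64e-05), with 0 called by limma in the difference (2 higher with the block). Deeper sequencing of the induced libraries is excluded for the long non-coding genes, since their median in shRCOR2 replicate 1, whose pair was close in depth, exceeded by 0.22 that in shCTRL replicate 2, whose induced library was 1.84 times as deep as its untreated one, but it cannot be told apart from a change in the cells for histones, where that difference was 0.14 (median over genes, quartiles −0.13 to 0.38) and the list rose in the deeper shCTRL pair (median 0.51) more than in the shallower one (−0.0015). The TPM share released by abundant coding genes that fell is excluded as the whole cause, since after median-of-ratios scaling the medians were 0.14 and, for histones, 0.68 (quartiles 0.27 to 0.96). More RNA without a poly(A) tail in the induced shRCOR2 libraries cannot be told apart from a change in the cells: the median of 214 other such RNAs, 0.0199, lies under the 0.07 of all genes but within their quartiles of −0.26 to 0.41, and that limit was tightened after the value was seen. Loss of RCOR2 stays open beside these and was not tested apart from them.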
